A study of Danio rerio with 3 samples.

How the data were processed

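RNA was extracted from whole larvae at 7 days post fertilization, 30 per group, with a silica-column kit that removes genomic DNA, and libraries followed the standard Illumina workflow, per the labels' protocols. There were 3 libraries, 1 each of wild-type control, serpini1 knockout and serpini1 transgenic larvae, all kept in 40 µg/mL doxycycline from day 3 to day 7. Groups were taken from the sample titles. HISAT, StringTie, DESeq2 and the genome build GRCz11 are named in the submitters' processing notes, with no version or role for any of them. Which of these tools made which values, and whether strand was used, is not given in the sources used here.

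The authors deposited FPKM (mapped fragments scaled to transcript length and to the depth of the library), per the file headers, rounded to 2 decimals. The table of all libraries used here holds 19699 complete genes, is sorted by the knockout value and ends in the middle of a line, so genes under 0.58 FPKM in the knockout are not in it. A deposited comparison of the transgenic with the control library lists 24529 genes with both FPKM values, the gene length in bases, a log2 ratio, a p-value and an FDR, per the file headers. A deposited comparison of the knockout with the control lists 266 genes with the same columns, and in its values every FDR is under 0.001 and every absolute log2 ratio at least 1. In both comparisons the authors wrote an FPKM of 0 as 0.01. The comparison method named for these tables is based on the Poisson distribution, going by the names of the deposited tables. The authors' p-values rest on 1 library per group and were not used as tests of a condition.

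Joined by gene identifier, the tables gave 24555 genes, and FPKM values of a gene in different tables differed by no more than rounding. Knockout values for 40 genes came from the deposited comparison alone, the highest at 0.56 FPKM. For 4816 genes no knockout value was used, and 217 of them had at least 1 FPKM in control. Gene symbols were those of the deposited tables. Of 1461 symbols written in the gene lists, 1274 matched there, 106 matched through the symbols and 8 through the synonyms of the RefSeq gene table of the assembly GRCz12tu, joined on the gene identifier. That assembly is not the authors' build, so it served for names and for the order of neighbouring genes, and no coordinates are given.

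The files give no read counts. The depth was inferred from the authors' p-values of genes listed at 0 in the control, which under a Poisson comparison fix the number of reads in the other library. All of these, 596 genes in the transgenic and 15 in the knockout comparison (100% each), lay within 0.05 of a whole number of reads once the ratio of depths was fitted. Over 71 genes with at least 10 such reads, the depth from FPKM, gene length less an offset of 100 bases and reads had a coefficient of variation of 3.84%. It came to about 7740000 fragments for the control, 7760000 for the knockout and 7980000 for the transgenic library. Reads per gene were estimated from FPKM with these depths and rounded. Their ratios have 95% Clopper-Pearson intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules and pools of larvae vary. Counting error at this depth was only a part of the spread. Among genes with at least 1000 reads summed over the libraries compared, counting error alone gave a robust SD of log2 ratios of 0.057. The observed SD was 0.18 for the knockout and 0.35 for the transgenic library. It also holds differences between groups and pools, so it is not a measure of precision.

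The size of a difference was log2((FPKM + 1) / (FPKM + 1)), a scale that understates ratios of genes with low values. Genes with at least 1 FPKM in either library were compared, and a gene counted as higher or lower when the absolute value was at least 1 (a 2-fold difference). FPKM was used as deposited. The median ratio of genes at 5 FPKM or more in both libraries was -0.03 for the knockout and 0.03 for the transgenic over control. Fold values in the text are ratios of FPKM without the pseudocount, and no fold is given against a gene listed at 0. Only 1 library per group exists, so no test between conditions was run.

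Before the data were examined, 37 gene lists of cell types, pathways and processes were fixed. For each list with at least 5 measured genes the median log2 ratio was ranked among 10000 random lists of the same size, drawn from 20 bins of mean expression (seed 1), and its percentile is given. A list stood apart when its median lay outside the central 99% of the random lists. The lists of the mitochondrial genome and of vitellogenins had too few measured genes, which left 35. Some genes belong to several lists, most of all the liver list, where 17 of 46 members are in another list. The percentile describes these libraries only. Genes named in the text were chosen by a rule fixed at the same time. It takes serpini1, the 8 highest and 8 lowest log2 ratios among genes of at least 5 FPKM in the higher library with a name that is not a clone or locus name, the 4 members with the largest ratio in the direction of the median for each list that stood apart, up to 2 members past the 2-fold rule for other lists, and 6 genes of each pattern for the comparison of directions. It gave 78 genes for the knockout and 121 for the transgenic comparison, and the text names a part of them; some genes the rule takes are not reported here. Families with near-identical copies, such as crystallins, globins and trypsins, are uncertain gene by gene.

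For genes in both comparisons, which share the control library, 100 sets of unchanged libraries were simulated from Poisson counts at the inferred depths, with an added coefficient of variation of 0, 0.1, 0.2 or 0.3. The alternatives tried were pseudocounts of 0.1 and 0.01 FPKM, no floor, a floor of 5 FPKM, ratios centred on their median or on a mean trimmed by 30% each side, FPKM rescaled to the same sum in each library (TPM), an absolute log2 ratio of at least 2, values summed per symbol, and random lists matched on length as well. Added after seeing the data were missing knockout values set to their bound, the table of all libraries alone, genes listed at 0 left out, at least 50 estimated reads, and the 100 or 50 measured neighbours of serpini1 on each side. The steps were tested on simulated data made from the transgenic and control means. Of genes raised 1.5-fold, a size under the rule, 0% of 67, raised 2-fold 25.4% of 67 and raised 4-fold 100% of 66 passed the rule. From counting error alone, 0.176% of 18743 unchanged genes did so. Of 40 unchanged lists 0 stood apart, and of 40 lists shifted by 0.3 on the log2 scale all 40 did. Genes varied independently of one another in these simulated data, which do not show how often lists of related genes stand apart. Only counting error was simulated, which is less than the spread seen in these libraries. The shares above are therefore not rates of false calls or of detection in these libraries. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Count models were not used, since FPKM values are not counts, and genes within a fixed distance of serpini1 were not analysed, since no annotation of the authors' build was used here.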

Results

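The series measured transcripts of whole zebrafish larvae at 7 days post fertilization in 3 groups on the AB background. The control group was wild type. The knockout group was titled as homozygous mutant for serpini1, while its genotype label sets the same symbol in the notation of a transgene, and the kind of mutation was not given in the sources used here. Serpini1 encodes neuroserpin, a serine protease inhibitor of the nervous system that blocks tissue-type plasminogen activator. The transgenic group carried a doxycycline-dependent Tet-On driver under the huC (elavl3) promoter, which is active in neurons, and a responder that expresses serpini1 with the red fluorescent protein mKate2. All 3 groups were bathed in 40 µg/mL doxycycline from day 3 to day 7, so the drug itself did not differ between them. Each group gave 1 library from the RNA of 30 pooled larvae. There were therefore no replicate libraries, and no difference below has a replicate check or a p-value. The depth inferred from the deposited values was about 7740000 fragments for the control, 7760000 for the knockout and 7980000 for the transgenic library. Intervals given beside fold values are 95% Clopper-Pearson intervals on reads estimated from that depth. They cover counting error only, not the variation between pools of larvae.

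The targeted gene was examined first, since its level checks the labels. Serpini1 (gene identifier 557627, transcript length 2168 bases) stood at 20.04 FPKM in the control library, with a counting interval of 17.9 to 22.4. It stood at 8.05 FPKM in the knockout (6.71 to 9.55) and at 288 FPKM in the transgenic library (279.95 to 296). The knockout level was 2.49-fold lower than control (interval 2.03 to 3.08), so transcript of the gene was still present in that library. The transgenic level was 14.4-fold higher than control (12.8 to 16.1). FPKM of a whole gene does not separate the transgene from the endogenous copy, and a transcript level does not show whether protein was made. The authors' deposited table gave log2 ratios of -1.32 for the knockout (FDR 9.59e-20) and 3.85 for the transgenic library (FDR 0).

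**Figure D1:**
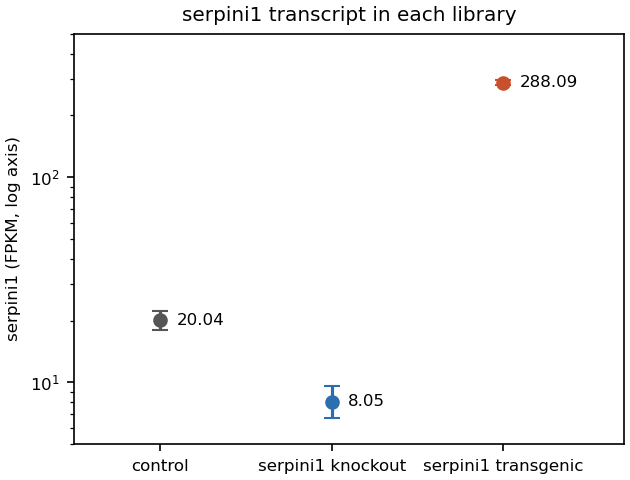
Level of the serpini1 transcript in FPKM (log axis) in the control, knockout and transgenic libraries; each point is 1 library of 30 pooled larvae and each bar is the 95% counting interval on its estimated reads. The levels were 20.04, 8.05 and 288 FPKM, and the 3 intervals do not overlap.

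The first comparison asked which transcripts differ between larvae labelled serpini1 knockout and wild type. The list medians of cartilage, bone and extracellular matrix genes and of DNA replication and cell division genes were higher in the knockout library, and those of macrophage and neutrophil markers and of inflammation genes were lower, while at most 5 members of each of these lists were past the 2-fold rule. Lists of neuronal genes lay within the range of random lists. Of 18663 genes with at least 1 FPKM in either library, 149 were at least 2-fold higher in the knockout and 123 at least 2-fold lower on the scale of log2(FPKM + 1), which is 1.46% of the genes. The balance turned with a floor of 5 FPKM, at 58 higher and 69 lower.

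Of 53 measured matrix genes, 44 had a ratio above 0 and 2 were past the rule, all on the higher side, and the median log2 ratio was 0.31, above all 10000 random lists matched on expression (percentile 100). Lumican (lum), a proteoglycan that binds collagen fibrils, was 2.19-fold higher in the knockout (1.77 to 2.69, 9.02 FPKM in control). The cartilage collagen genes col9a3 and col11a2 were 2.04-fold (1.86 to 2.24) and 1.86-fold higher (1.70 to 2.04). In the list of DNA replication and cell cycle genes, 41 of 51 lay above 0 and 3 were past the rule on the higher side, with a median of 0.27 at percentile 100. It included mcm7, a subunit of the replicative helicase, 1.70-fold higher (1.56 to 1.87), and the mitotic kinase gene aurkb at 2.63 and 6.45 FPKM.

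Genes of intestinal absorption were shifted upwards, with 31 of 47 above 0, a median of 0.16 at percentile 100 and no member past the 2-fold rule. Among them, npc1l1, the sterol importer of the gut, stood at 8.07 FPKM in control and 15.5 in the knockout, the peptide transporter gene slc15a1a at 11.2 and 20.6, and dgat2, which makes triglyceride, at 24.1 and 39.8. The list of fatty acid oxidation and fasting genes had a median of 0.08 (percentile 99.6) over 41 genes. The lipase inhibitor gene angptl4 was its 1 member past the rule, 2.32-fold higher in the knockout (1.94 to 2.78), and cpt1b, which takes fatty acids into mitochondria, was 1.80-fold higher (1.45 to 2.25). Exocrine pancreas enzymes had a median of 0.10 (percentile 99.6), with 22 of 32 above 0 and 0 past the rule. The bile salt-activated lipase gene cel.2 stood at 132 FPKM in control and 241 in the knockout, and the elastase gene ela2 at 1634 and 2332.

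Among 29 macrophage and microglia markers, 24 lay below 0 in the knockout and 1 was past the rule, with a median of -0.35 at percentile 0. The lysosomal protease gene ctss2.1 was 2.46-fold lower (1.6 to 3.86), and irf8, a transcription factor that macrophages need, was 2.98-fold lower (1.31 to 7.74, from 1.88 FPKM in control). Neutrophil markers had 14 of 16 below 0, 0 past the rule and a median of -0.42 at percentile 0. Myeloperoxidase (mpx) stood at 5.31 FPKM in control and 2.67 in the knockout. The list of inflammation and acute phase genes had 33 of 38 below 0, 5 past the rule and a median of -0.35 at percentile 0. Hepcidin (hamp), the iron hormone of the liver, was at 5.78 FPKM in control and listed at 0 in the knockout. The C-reactive protein gene crp3 was 4.21-fold lower (3.04 to 5.99), and socs1a, a feedback inhibitor of cytokine signalling, 2.16-fold lower (1.72 to 2.69).

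Coagulation and thrombocyte genes had 18 of 24 below 0 in the knockout, 0 past the rule and a median of -0.22 (percentile 0.06). Tissue factor f3a stood at 6.56 FPKM in control and 3.48 in the knockout. Lens crystallins had 37 of 49 below 0, a median of -0.15 at percentile 0, and 2 members past the rule. The crystallins share near-identical copies whose reads can be split between them, so values of single crystallins are uncertain.

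The medians of the other lists lay inside the central 99% of their random lists in the knockout. For the nervous system these were -0.04 for pan-neuronal genes, -0.08 for the glutamatergic synapse, -0.08 for the GABA and glycine synapse, 0.11 for monoamine and cholinergic neurons, -0.05 for neuropeptides, 0.04 for glia and myelin and 0.02 for photoreceptors. Genes of plasminogen activation had a median of -0.03. The circadian clock was at -0.06, the interferon response at 0.01, immediate early genes at -0.13, the pituitary and interrenal axis at -0.15 and erythrocyte genes at -0.14. Liver secretory genes were at -0.06, endocrine pancreas and gut hormones at 0.02, cholesterol synthesis at 0.02, lipogenesis and glycolysis at 0.08, the unfolded protein response at -0.05 and the heat shock response at -0.10. Skeletal muscle was at 0.05, cardiac muscle at 0.00, epidermis at 0.05, the p53 response at 0.02, oxidative stress and xenobiotic genes at -0.00 and pigment cells at -0.02.

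Single members of these lists were past the rule. The immediate early genes junbb and klf4 were 2.47-fold (2.21 to 2.76) and 2.61-fold lower (1.958 to 3.54) in the knockout. The Notch target her4.2 of neural progenitors stood at 0.88 FPKM in control and 3.63 in the knockout. The low-density lipoprotein receptor gene ldlrb stood at 6.80 and 2.65 FPKM, the fatty acid desaturase gene scd at 1.76 and 0.13, and heme oxygenase hmox1a at 8.06 and 3.43. The pigment genes tyrp1a (melanin) and gch2 (pteridine) were 2.36-fold (1.82 to 3.06) and 2.19-fold higher (1.80 to 2.67).

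Genes named for the size of their ratio alone were led on the higher side by sagb, an arrestin of photoreceptors, at 0.30 FPKM in control and 8.25 in the knockout. Complement factor D (cfd) was 6.90-fold higher (4.28 to 12.26), the zinc-sensing receptor gene gpr39 5.36-fold (4.22 to 6.86), the cell surface glycoprotein gene thy1 4.17-fold (2.61 to 7.17) and ecrg4a, which encodes a secreted peptide precursor, 3.51-fold (2.43 to 5.34). The cohesin gene smc1a was listed at 0 in control and at 5.08 FPKM in the knockout, and a 0 in such a table can be a failed estimate. On the lower side, mal, a proteolipid of myelin and epithelia, stood at 5.53 FPKM in control and was listed at 0 in the knockout. The paraoxonase gene pon3 was 12.11-fold lower (5.05 to 39.6), the mitochondrial termination factor gene mterf3 11.4-fold (5.10 to 28.3) and rgs2, a regulator of G protein signalling, 4.87-fold (3.39 to 7.26). The cone phosphodiesterase subunit pde6h stood at 337 FPKM in control and 87.1 in the knockout.

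The deposited table of all libraries gave no knockout value under 0.58 FPKM, and 217 genes with at least 1 FPKM in control have none, of which 15 would pass the rule at that bound. The exocrine pancreas list was inside the random range when the random lists were matched on gene length as well, and the fatty acid oxidation (0.02) and coagulation (-0.19) lists were inside it with a floor of 5 FPKM, while erythrocyte genes (-0.26) and lipogenesis and glycolysis (0.12) were outside it with that floor, and lipogenesis and skeletal muscle with the length match.

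The second comparison asked which transcripts differ between larvae of the transgenic group and wild type. The transgenic larvae differ from control by the Tet-On driver and mKate2 as well as by serpini1. No group carried the driver or mKate2 without serpini1, so their effects cannot be told apart. The list medians of inflammation, interferon response, leukocyte and DNA replication genes were higher in the transgenic library. Those of pan-neuronal and synaptic genes, clock genes, lens crystallins and exocrine pancreas enzymes were lower. Few members were past the 2-fold rule in some of the lower lists, with 0 of 42 pan-neuronal genes and 1 of 52 lens crystallins. Among genes named for the size of their ratio, the leptin gene lepb stood at 0.38 FPKM in control and 32.2 in the transgenic library. Mmp13a and mmp9, secreted proteases that cleave collagen and gelatin, were 25.3-fold (19.4 to 33.3) and 24.1-fold higher (19.96 to 29.7). Of 19242 genes at 1 FPKM or more in either library, 684 were higher and 241 lower by the 2-fold rule, or 4.81% of them.

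Of 47 measured inflammation and acute phase genes, 42 lay above 0 and 22 were past the rule, with a median log2 ratio of 0.96 at percentile 100. Serum amyloid A (saa) was listed at 0 in control and at 25.9 FPKM in the transgenic library. Interleukin 1 beta (il1b) was 46.9-fold higher (22.5 to 117), timp2b, an inhibitor of metalloproteases, 19.3-fold (15.2 to 25.2), and irg1l, which makes itaconate in activated phagocytes and skin, 10.5-fold (7.32 to 15.3). Interferon response genes had 31 of 34 above 0, 16 past the rule and a median of 0.93 at percentile 100. The ubiquitin-like isg15 was 9.06-fold higher (4.75 to 19.6), and the antiviral GTPase gene mxb was listed at 0 in control and at 3.28 FPKM in the transgenic library. In every list, members under 1 FPKM in control, such as mxb, are measured only where they reach 1 FPKM in the transgenic library. Their ratios therefore lie above 0 in advance. Against the knockout library, 20 interferon genes were measured and 4 were past the rule, with a median of 0.64. Outside these lists, cfd stood at 2.91 FPKM in control and 37.6 in the transgenic library, and tnfaip2b at 0.57 and 12.15.

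Markers of blood cells moved with these lists. Among macrophage and microglia markers 31 of 32 lay above 0 and 11 were past the rule (median 0.74, percentile 100). The pore-forming protein gene mpeg1.2 was 8.93-fold higher (6.54 to 12.7), the granulin gene grn2 7.40-fold (4.45 to 14.1) and mfap4 6.22-fold (4.08 to 9.76). Neutrophil markers had 15 of 17 above 0, with 5 past the rule on the higher side and 1 on the lower (median 0.69, percentile 100). The chemotactic lect2l stood at 21.6 FPKM in control and 115 in the transgenic library, and srgn, the core protein of secretory granules, at 16.8 and 39.7. Erythrocyte genes had 21 of 24 above 0 and a median of 0.46 at percentile 100, although the globins among them share near-identical copies and are uncertain one by one.

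All 55 measured genes of DNA replication and cell cycle lay above 0 in the transgenic library, 16 of them past the rule, with a median of 0.79 at percentile 100. Aurkb was 3.99-fold higher (2.5 to 6.72), tyms, which makes thymidylate, 3.60-fold (2.02 to 6.90) and the helicase subunit gene mcm4 2.69-fold (2.24 to 3.23). The p53 response list had a median of 0.29 (percentile 99.8), with the cell cycle inhibitor cdkn1a at 14.7 FPKM in control and 26.3 in the transgenic library. Genes of protein folding in the endoplasmic reticulum and the heat shock response had medians of 0.38 (percentile 100) and 0.34 (percentile 99.98). The collagen chaperone gene serpinh1b was 5.19-fold higher (4.16 to 6.54), the small heat shock protein gene hspb1 3.60-fold (2.81 to 4.67), the disulfide isomerase gene pdia4 3.22-fold (2.57 to 4.04) and hsp90b1 2.21-fold (2.01 to 2.44).

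The list of serpini1 and plasminogen activation genes, which serpini1 itself belongs to, had 6 of 23 members past the rule on the higher side and a median of 0.51 at percentile 100. Anxa2a, which binds plasminogen at the cell surface, was 2.62-fold higher (2.41 to 2.85). Liver secretory genes had a median of 0.41 at percentile 100, with transferrin (tfa) at 292 FPKM in control and 792 in the transgenic library and the fibrinogen chain gene fgb at 60.6 and 141. The list of lipogenesis and glycolysis had a median of 0.30 (percentile 99.97), with hexokinase hk2 2.63-fold higher (2.0 to 3.45). Epidermis and keratin genes had 9 members higher and 2 lower past the rule and a median of 0.26 (percentile 99.93). The mucus-cell gene agr2 was 2.83-fold higher (2.26 to 3.55) and krt96 3.60-fold (2.67 to 4.84). Matrix genes had 45 of 53 above 0 and a median of 0.35 at percentile 100, with col9a3 2.14-fold (1.95 to 2.34) and the fibronectin gene fn1a 2.16-fold higher (1.97 to 2.36). Oxidative stress and xenobiotic genes had a median of 0.24 (percentile 99.54), with cyp1a, a target of the aryl hydrocarbon receptor, at 29.6 and 85.7 FPKM, and gstp1 at 98.1 and 236.

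Genes of the pan-neuronal and synaptic lists were lower in the transgenic library by small amounts, and none of them was past the rule. Of 42 pan-neuronal genes 36 lay below 0 (median -0.20, percentile 0.02). The synaptic vesicle gene sv2a was 1.65-fold lower (1.53 to 1.79) and the calcium sensor of vesicle release syt1a 1.49-fold (1.4 to 1.59). The glutamatergic synapse list had 31 of 33 below 0 and a median of -0.43 at percentile 0, with the AMPA receptor gene gria4a 2.04-fold lower (1.62 to 2.59). The GABA and glycine synapse list had 33 of 35 below 0 and a median of -0.34 at percentile 0. Its member gad2, which makes GABA, was 1.72-fold lower (1.58 to 1.88). Photoreceptor genes had a median of -0.17 (percentile 0.10) with the cone arrestin arr3b at 99.9 FPKM in control and 56.0 in the transgenic library, and lens crystallins a median of -0.31 at percentile 0 with 47 of 52 below 0.

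Clock genes held the largest single ratio on the lower side among the genes named by size. Per2, a period gene that light induces in fish, was 17.6-fold lower in the transgenic library (14.3 to 21.7), at 40.7 FPKM in control and 2.31 in the transgenic. The cryptochrome and photolyase family genes cry1bb and cry5 were 7.28-fold (5.22 to 10.3) and 6.48-fold lower (4.52 to 9.65), and npas2, a partner of bmal proteins, 4.16-fold (2.98 to 5.88). The clock list had 8 of 42 members past the rule, all lower, 31 below 0 and a median of -0.37 at percentile 0. Outside the list, lonrf1 was 10.9-fold lower (7.69 to 15.4), the proteasome activator gene psme4a 5.84-fold (5.05 to 6.77) and nr0b2a, a nuclear receptor of bile acid metabolism, 7.07-fold (4.51 to 11.2). The elongin gene tceb3 stood at 34.1 FPKM in control and 9.72 in the transgenic library, and the helicase gene ddx41 at 6.34 and 0.91.

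Exocrine pancreas enzymes had the lowest median of any list in the transgenic library, -0.97 at percentile 0, with 30 of 33 below 0, 14 past the rule on the lower side and 1 on the higher. Carboxypeptidase A1 (cpa1) was 2.75-fold lower (2.43 to 3.1), cel.1 2.45-fold (2.34 to 2.57) and the trypsin-like zgc:92745 5.24-fold (4.36 to 6.30), although trypsins have near-identical copies and are uncertain one by one. In contrast, the proglucagon gene gcga of the islet was 9.73-fold higher (7.39 to 13.1), while the list of endocrine pancreas and gut hormones had a median of 0.03.

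That list and the following ones lay inside the central 99% of random lists. Medians were -0.05 for monoamine and cholinergic neurons, -0.02 for neuropeptides, -0.11 for the pituitary and interrenal axis, 0.16 for immediate early genes, 0.06 for glia and myelin, 0.07 for intestinal absorption, 0.26 for cholesterol synthesis, 0.17 for fatty acid oxidation, -0.01 for skeletal muscle, 0.08 for cardiac muscle, 0.23 for coagulation and 0.04 for pigment cells. Members past the rule included cyp51, a demethylase of sterol synthesis, 6.47-fold higher (4.50 to 9.27), and the immediate early genes fosl1a and junba, 4.67-fold (3.63 to 6.13) and 2.37-fold higher (2.1 to 2.66). The muscle ubiquitin ligase gene fbxo32 was 2.89-fold lower (2.48 to 3.37) and angptl4 3.74-fold higher (3.16 to 4.44).

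Of 35 lists scored, 22 stood apart from random lists in this comparison and 10 in the knockout. For each, 0.35 would do so if the genes of a list varied independently of one another. Genes of a list can vary together between single pools, which random lists do not copy, so these counts are not measured against chance. The p53 list was inside the random range with a floor of 5 FPKM or with lists matched on length, and the oxidative stress list in those settings and with a pseudocount of 0.1 FPKM, while cholesterol synthesis (0.49) was outside it with that pseudocount and coagulation (0.35) with that floor.

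**Figure D2:**
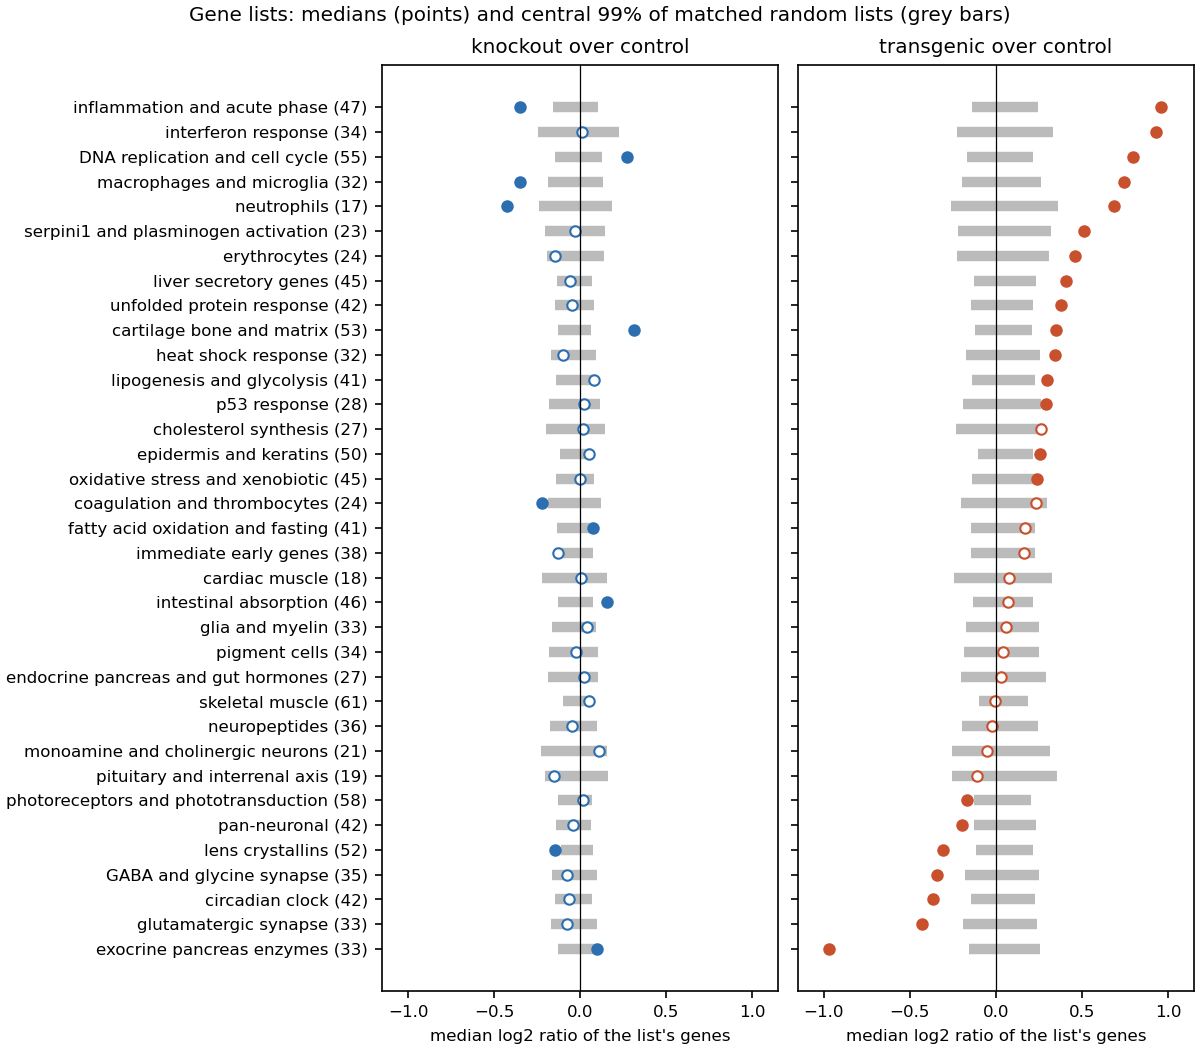
Median log2 ratio of each gene list, knockout over control (left) and transgenic over control (right), with the number of genes measured in the transgenic comparison in parentheses; grey bars span the central 99% of 10000 random lists matched on expression, and filled points lie outside them. Inflammation lies at -0.35 in the knockout and 0.96 in the transgenic library, and exocrine pancreas enzymes at 0.10 and -0.97.

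**Figure D3:**
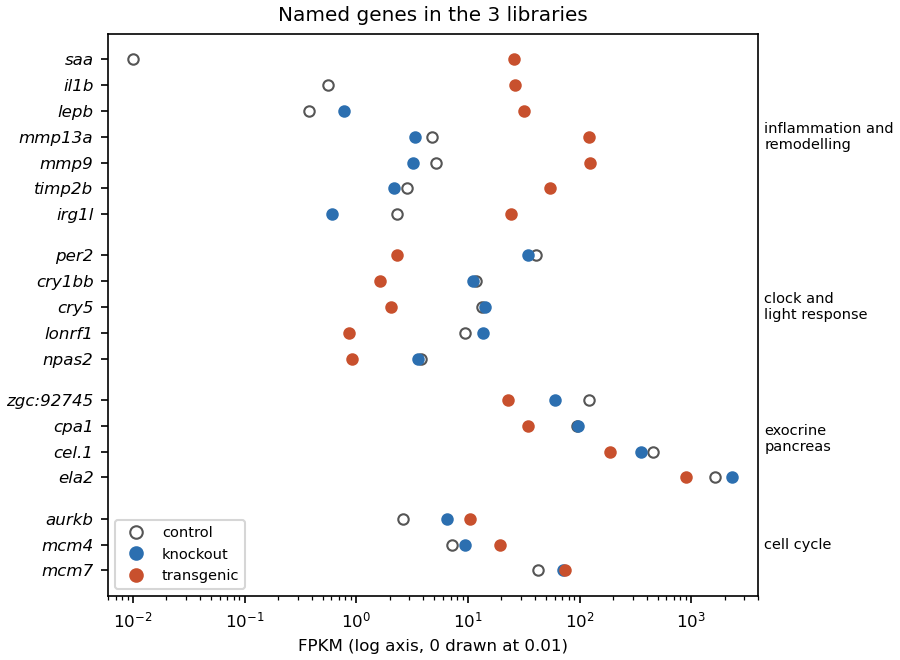
FPKM (log axis, with 0 drawn at 0.01) of named genes in the control, knockout and transgenic libraries, 1 library each; no knockout point is drawn for saa and il1b, which have no knockout value here. Per2 was at 40.7 FPKM in control and 2.31 in the transgenic library, and mmp9 at 5.16 and 124.

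Both comparisons use the same control library. Of 7 lists apart in both, 3 went in the same direction and 4 in opposite directions. The 3 were matrix genes, DNA replication genes and lens crystallins, and the shared control may account for part of their shifts. The question of opposite directions was examined over 18337 genes with values in all 3 libraries that met the floor of 1 FPKM in both comparisons. Lower in the knockout and higher in the transgenic library were 13 genes, which include serpini1, hamp, irg1l, krt96 and odc1, the enzyme that starts polyamine synthesis. Odc1 was at 27.7 FPKM in control, 12.12 in the knockout and 96.8 in the transgenic library. There were 0 genes past the rule the other way round. In the same direction in both were 83 genes, 59 higher and 24 lower. Higher in both were cfd, sagb, thy1, stra13, fads2, a desaturase of polyunsaturated fatty acids, and cox4i1l. Fads2 was 3.11-fold higher in the knockout (2.25 to 4.31) and 3.2-fold in the transgenic library (2.31 to 4.42). Lower in both were pdk1, which inhibits pyruvate dehydrogenase, gch1, the first enzyme of biopterin synthesis, pon3, ddx41, and the crystallins crygm2b and crygm2c. Pdk1 stood at 23.0 FPKM in control, 5.87 in the knockout and 6.96 in the transgenic library, and gch1 at 12.7, 3.99 and 5.01.

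Independent lists of these sizes would share 4.64 genes in the same direction and 4.81 in opposite directions. Simulated unchanged libraries with the shared control gave 2.29 same and 0 opposite genes from counting error alone. With an added coefficient of variation (CV) between libraries of 0.1, 0.2 and 0.3 they gave 3.14, 28.9 and 279 same and 0.01, 0.01 and 1.06 opposite genes. Across genes, which are not independent replicates, the log2 ratios of both comparisons correlated with Pearson r 0.39 and Spearman rho 0.40, against r 0.50 in the simulation at each of these settings. The covariance was 0.063, against 0.018 simulated from counting error alone and 0.033, 0.076 and 0.15 with those CVs. With 1 control library it could not be split, and part of the excess of shared genes may come from it.

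**Figure D4:**
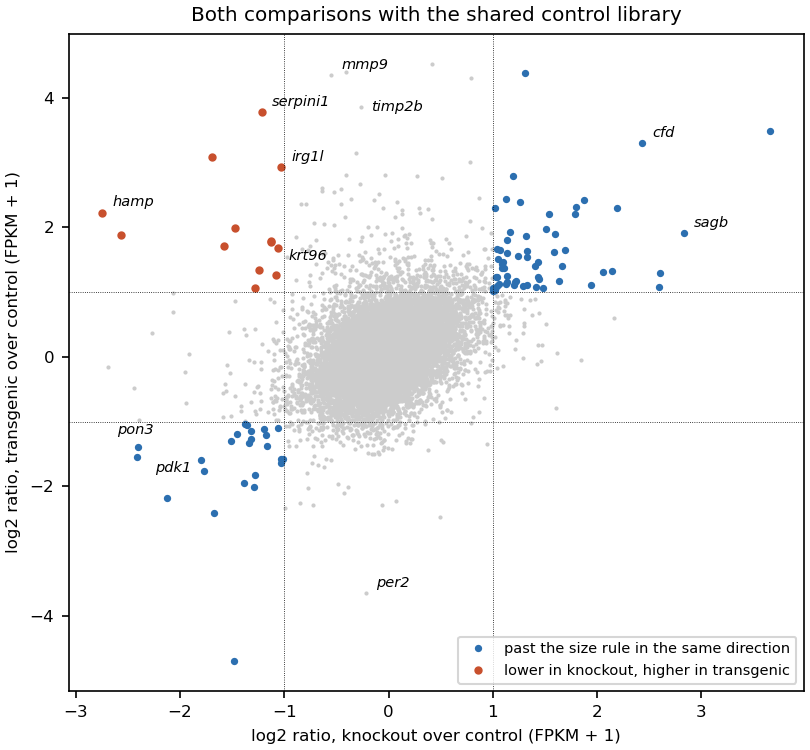
Each point is a gene, with its log2 ratio of FPKM + 1 in the knockout over control on the x axis and in the transgenic over control on the y axis; dotted lines mark the 2-fold rule. Blue points are the 83 genes past the rule in the same direction and red points the 13 genes lower in the knockout and higher in the transgenic library; the lower right corner holds 0 genes.

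The transgenic library was also set against the knockout, which does not use the control. The list medians of leukocyte, inflammation and erythrocyte genes were higher in the transgenic library, and those of exocrine pancreas enzymes and clock genes lower. Inflammation genes had 25 of 39 past the rule on the higher side (median 1.19, percentile 100), macrophage markers 16 of 30 (1.04, percentile 100), neutrophil markers 8 of 17 (0.88, percentile 100) and erythrocyte genes 9 of 23 (0.88, percentile 100). Exocrine pancreas enzymes had 19 of 32 past it on the lower side (-1.01, percentile 0) and clock genes 6 of 42 (-0.43, percentile 0). Of 18775 genes, 537 were higher and 202 lower. Genes without a knockout value, il1b and saa among them, are left out of this comparison and its lists. With missing knockout values set to their bound, 631 genes were higher and 202 lower.

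DNA replication genes had 51 of 54 above 0 (median 0.54). Other lists apart on the higher side were the interferon response (0.64), heat shock (0.57), coagulation (0.46), serpini1 and plasminogen activation (0.34), the unfolded protein response (0.34), oxidative stress (0.33), liver secretory genes (0.33) and epidermis (0.30). On the lower side were the glutamatergic synapse (-0.37), the GABA and glycine synapse (-0.27), pan-neuronal genes (-0.19) and lens crystallins (-0.12). The list median of matrix genes, which was above control in both libraries, was 0.07 here and lay inside the random range. That of photoreceptor genes, -0.08, also lay inside it, but outside with lists matched on length. The plasminogen activation list was inside it with a pseudocount of 0.1 FPKM or a floor of 5 FPKM.

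The authors' deposited table of called genes listed 778 genes as higher and 343 as lower in the transgenic larvae at an FDR under 0.001 and an absolute log2 ratio of at least 1. For the knockout the authors' deposited table listed 115 as higher and 151 as lower. Of the genes in the authors' deposited table, 89 were called in both comparisons, 76 in the same direction and 13 in opposite directions. These calls compare single libraries, not conditions with replicates.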

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

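All tests of explanations in this part were chosen after the results were seen. Results below stand out because the 2 comparisons with control go in opposite directions, and none of these differences was itself tested, since each group has 1 library. The median log2 ratio of macrophage and microglia markers was -0.35 in the knockout and 0.74 in the transgenic library. For neutrophil markers it was -0.42 and 0.69, and for inflammation and acute phase genes -0.35 and 0.96. Exocrine pancreas enzymes went the other way, with 0.10 in the knockout and -0.97 in the transgenic library. With random lists matched on length as well, the knockout value of that list lay inside the random range (percentile 99.3). Whether the list stands apart in the knockout, though not the sign of its median, therefore rests on the matching. Of single genes, 13 were lower in the knockout and higher in the transgenic library by the 2-fold rule, serpini1 among them.

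The list median of inflammation genes was higher in the transgenic library. An overall shift of scale from a few abundant genes is argued against by the median log2 ratio of genes at 5 FPKM or more, 0.027. Whether more leukocytes with unchanged gene activity could be the whole cause depends on which markers are kept. Of 44 members not listed at 0 in control, 22 have counting intervals above the median fold of the markers. These were 44 macrophage and neutrophil markers at 1 FPKM or more, of which 12 lie above that fold themselves. The list was flagged for its high median, so a larger share was likely in advance. Il1b and timp2b (from 22.5- and 15.2-fold up) lie above each of these markers (at most 14.1-fold, grn2). The induced genes mmp9 and mmp13a (up to 29.7- and 33.3-fold) were left out as markers. With them kept, neither il1b nor timp2b lies above every marker, so this cause stays open. More leukocytes also stay open as part of the cause for the 42 members other than il1b and timp2b. The median log2 ratio of those markers was 0.70, and the intervals of 11 of these members include the markers' median fold. With 1 transgenic library, an infection or injury of this pool alone may also contribute, and an effect of serpini1 was not tested. Effects of the driver or mKate2 cannot be told apart from one of serpini1.

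The list median of circadian clock genes was lower in the transgenic library, with 8 of 42 past the rule on the lower side, per2 most of all, and 11 above 0. If the larvae were collected at another time of day, genes of the morning and evening arms should part. Their medians of 0.07 and -0.77 differed by 0.84, less than the 1 set for a clear shift and more than the 0.5 set against it. The genes of both arms all belong to the flagged clock list, so their values are part of the pattern itself. If the larvae had received less light, light-induced genes should be lower. The 10 such genes had a median of -0.49, under the lowest bound of matched random lists (-0.31) but not past the -0.5 that was set. Most of them are also in the clock list, so neither test is independent of the flagged result. Both therefore stay open, a different time of collection or less light before collection may each contribute, and the labels give no time of collection. An effect of serpini1, the driver or mKate2 on the clock was not tested.

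Of the 18337 genes that met the floor of 1 FPKM in both comparisons with control, 235 were past the 2-fold rule in the knockout. Counting error alone gave 14.1 genes in simulated unchanged libraries, far fewer. For strain variants linked to the edited locus, up to 100 measured neighbours of serpini1 on each side were taken, in the gene order of another assembly. Of these 185 neighbours 1.08% were past the rule, against 1.46% of all genes compared, so no excess was seen near the locus. They made up 0.735% of the genes past the rule (2 of 272), a share that their small number limits. Differences between the lines elsewhere in the genome were not tested. Variation between pools of larvae stays open: unchanged libraries with an added coefficient of variation of 0.1, 0.2 or 0.3, the same for every gene, gave 22.0, 224 and 1250 genes, and the robust SD of log2 ratios across genes with 1000 reads or more, 0.18, was nearest the 0.21 simulated at 0.1, but no replicate pool shows how many genes vary by more than that. An effect of the lower serpini1 level is an untested alternative, so the knockout count may reflect either.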

How the results depend on the processing

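The settings with missing knockout values at their bound, the table of all libraries alone, genes listed at 0 left out, at least 50 estimated reads, and neighbours of serpini1 by gene order were added after the data were seen; the others were planned. Serpini1 kept its direction with both smaller pseudocounts and with centring, the settings run for it, and 0 list medians and 0 named genes reversed in theirs. A pseudocount cannot change the sign of a ratio, and centring moves every ratio by the same small amount. Neither could therefore reverse serpini1 or a gene past the rule. Centring also moves a list and its random lists together, so it could not change whether a list stood apart. Of 105 list medians scored, 48 lay inside the random range in every setting run; of the other 57, chosen for standing apart in at least 1 setting, 54 kept their call with a pseudocount of 0.1, 49 with a floor of 5 FPKM, 57 with ratios centred on the median and 51 with lists matched on length; of 197 named genes 180 kept theirs with a pseudocount of 0.1 and 193 with centring. With a pseudocount of 0.1 FPKM the counts past the rule were 832 for the knockout, 2088 for the transgenic and 1567 for the transgenic over the knockout, with 28 genes in opposite directions (4 of them higher in the knockout and lower in the transgenic library) and 291 in the same; with 0.01 FPKM they were 931, 2245, 1721, 32 and 326. A floor of 5 FPKM, which tests fewer genes, gave 127 for the knockout (58 higher and 69 lower), 534 for the transgenic and 30 in the same direction. Rescaling to a fixed sum gave 454 for the knockout and 149 in the same direction. The deposited FPKM sums were similar (640582 for control, 650713 for the knockout and 646477 for the transgenic library) and lower than the fixed sum. Rescaling therefore raised all values while the pseudocount and floor stayed at 1, which acts like a smaller pseudocount and a lower floor. An absolute log2 ratio of 2 gave 20 (9 higher and 11 lower), 99 and 86, with 1 gene opposite and 4 the same, while the authors' deposited tables, on their own log2 scale without the pseudocount of 1 FPKM and with their FDR limit, held 89 and 326 genes for the knockout and the transgenic library past 2. At least 50 estimated reads gave 123 (54 higher and 69 lower), 584, 8 opposite and 27 the same. The correlation of the comparisons was 0.45 with a pseudocount of 0.1 and 0.37 with a floor of 5. Among neighbours of serpini1 with a pseudocount of 0.1, 4.86% passed in the knockout and 9.94% in the transgenic library, and 0% did in the knockout with 50 on each side. No filter, centring, a trimmed mean, summed symbols, bounds for missing values, the single table and no zeros left every count within 1.5 times, although without zeros the knockout had 111 higher and 116 lower. Ratios of read counts were not run, since the files give no counts, and windows of 2, 5 and 10 Mb around serpini1 were not run. Depth limits single genes: in the knockout the interval of stra13 runs from 1.58- to 19.2-fold and that of pde6h, lower there, from 3.44- to 4.36-fold.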

Other observations

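The test of a gene-by-gene relation at the end of this part was chosen after the result was seen, and the genes of the next paragraphs were chosen after their values were seen, outside the rule for named genes. Genes of skin ionocytes, the cells that take up ions from the water, differed in the transgenic library in both directions, with 6 of 32 past the rule on the higher side and 3 on the lower. The epithelial calcium channel gene trpv6 was 8.57-fold higher (6.70 to 11.1), kcnj1a.5, a potassium channel gene, 4.42-fold (3.15 to 6.32), and the sodium pump gene atp1a1a.2 3.49-fold (3.18 to 3.83). The others past the rule on that side were kcnj1a.4, kcnj1a.6 and igfbp5a, while foxi3a, which specifies ionocytes, was 2.09-fold higher (1.55 to 2.83) and not past it on the pseudocount scale. The ammonia transporter genes rhcga and rhcg2a were 2.2-fold (2.08 to 2.34) and 2.26-fold lower (2.04 to 2.51), and the carbonic anhydrase ca15c 3.46-fold lower (2.41 to 5.05). In the knockout 0 of 31 measured genes of this group were past the rule. The kcnj1a and atp1a1a genes lie in tandem copies and are uncertain one by one. Past the rule on the higher side in the transgenic library were 2 of 6 prostaglandin genes, 2 of 3 leptin genes (the receptor gene lepr was not) and 2 of 3 inflammasome genes (caspa was not). The prostaglandin E synthase gene ptges was 4.42-fold (3.33 to 5.89) and the cyclooxygenase gene ptgs2a 2.97-fold higher (2.55 to 3.47), and the leptin gene lepa stood at 0.50 FPKM in control and 7.81 in the transgenic library. Of the inflammasome, caspb was 3.04-fold (2.60 to 3.58) and the adaptor pycard 2.44-fold higher (1.91 to 3.16), and of 7 polyamine genes 2 were past the rule, odc1 and sat1a.2, the latter 2.46-fold higher (2.2 to 2.75). In the knockout 1 gene of these 4 groups was past the rule, odc1, on the lower side.

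Of 3 genes of photoreceptors looked at, six7, a transcription factor of green cones, was 3.15-fold lower in the transgenic library (2.66 to 3.73) and tulp1b 3.80-fold lower (3.05 to 4.76), while tulp1a stood at 6.21 FPKM in control and 6.76 in the transgenic library. In the knockout six7 and tulp1b stood at 16.5 and 6.88 FPKM against 18.6 and 7.37 in control. Of 19 genes tied to retinoic acid, 2 were past the rule in the knockout, cyp26a1, which degrades retinoic acid, 2.31-fold lower (1.71 to 3.11) and the retinal reductase gene dhrs3a 2.30-fold lower (1.73 to 3.06), and 1 in the transgenic library, the retinol dehydrogenase gene rdh1, at 44.3 FPKM in control and 20.5 in the transgenic. Of 4 sterol export genes, 0 were past the rule in the knockout and 1, abcg1, in the transgenic library, and the values of all 4 lay below control in both. The transporter genes abcg5 and abcg8 stood at 10.8 and 6.88 FPKM in control, 5.03 and 3.03 in the knockout, and 6.21 and 4.15 in the transgenic library. Abcg1 stood at 14.1, 8.75 and 6.12 FPKM, and abca1a at 54.4, 30.0 and 35.1, in the same order of libraries. Since both ratios share 1 control library, a high control value would give the same picture.

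A hypothesis is that leukocyte and inflammation genes follow the serpini1 level gene by gene, so that members lower in the knockout are the ones most raised in the transgenic library. The macrophage, neutrophil and inflammation lists have 83 members measured in both comparisons. Of these, 64 were below 0 in the knockout and above 0 in the transgenic library, 11 above 0 in both, 7 below 0 in both and 1 the other way. The lists were flagged for medians in these opposite directions, so a majority of such members was likely in advance. Across these members the Spearman correlation of the log2 ratios was -0.082, where random lists matched on expression gave 0.11 to 0.63 (middle 0.40). The random lists hold both the shared control and any difference common to both libraries, which could not be split. The value lies below that range, but not below the -0.22 set for a graded inverse relation, which therefore stays open.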
